A study of Mus musculus with 9 samples.

How the data were processed

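The 9 samples were bulk RNA-seq libraries from sensory neurons of neonatal mouse dorsal root ganglia, isolated by fluorescence-activated sorting of dissociated cells. They fell into 3 groups of 3 samples by reporter and Runx3 genotype, as the labels give them. Each sample came from 1 to 4 animals on a mixed C57/Sv129 background, with 1 animal each for 2 of the Rx3-/-;PV:tdT samples, and neonates of both sexes were used. Nothing in the labels tied a sample of one group to a sample of another. The labels do not say whether a litter or a sorting day was shared, so the p-values measure the spread between these samples, for 2 of them between single animals.

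The values came from 5 comparison tables, each with 23038 genes. Each table gave a log2 fold change, a mean log2 CPM, a p-value, an adjusted p and a flag per gene, as the authors deposited them. The same tables held 1 RPKM value per gene and group, which the authors deposited as group values without values per sample. For comparisons 1 and 3 the values taken as those of TrkC:GFP stand under the name Rx3, which does not match the group. They were assigned to TrkC:GFP because the tables' names give proprioceptors with SA-LTMRs and the values equal those given for the first 3 samples in comparison 4. Per the submitters' processing notes, reads were mapped to mm10 and edgeR was used. The aligner, the counting program, their versions, the kind of edgeR test and the rule for the group RPKM are not given in the sources used here. Per the labels' protocols, RNA was amplified before poly-A selected, single-end libraries were made.

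The deposited adjusted p equalled the Benjamini-Hochberg adjustment of the deposited p-value over all 23038 genes in every table. The sign of each fold change was checked against the deposited RPKM values: every called gene had the same sign in both. The authors' flag was nonzero only at an adjusted p under 0.01 and an absolute log2 fold change of 1 or more, but not for all genes inside those limits. The rule behind it is not given in the sources used here.

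Because the tables held no values per sample, the fits planned per sample were replaced by the fallback planned for that case. The comparisons, this fallback, the candidate sets, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. A gene was called where the authors' deposited edgeR adjusted p (Benjamini-Hochberg) was under 0.05, and all fold changes and adjusted p values below are the authors' own. Comparison 1 set TrkC:GFP against Rx3-/-;PV:tdT, comparison 2 set Rx3+/+;PV:tdT against Rx3-/-;PV:tdT, and comparison 3 set Rx3+/+;PV:tdT against TrkC:GFP. Comparison 4 set TrkC:GFP against both PV:tdT groups, and comparison 5 set TrkC:GFP with Rx3+/+;PV:tdT against Rx3-/-;PV:tdT. No standard error was given with the fold changes, and none could be computed.

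The deposited RPKM values of genes without reads were a fixed amount divided by a whole number, the gene's length, within a tolerance of 1e-06. That pattern is what 1 read added to each library before averaging would give, and it was used in 3 ways. Genes without reads in a group were identified. The library sizes behind the RPKM values were read off from the steps that single reads make. For 2577 genes without reads in at least 1 group, the reads per library of the other groups were recovered where exactly 1 combination of whole reads gave the value, which was so for 3827 of 3831 group values, or 99.9%. Libraries could be ordered by depth but not tied to a replicate number. Recovery was also tried on data simulated from the real group means, over all 3 groups and 23038 genes. There 99.8% of group values were recovered and 2 were recovered wrongly. Library sizes and most gene lengths were drawn at random in that simulation, so it was not run at the depths recovered here.

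Where all libraries of a group had no reads for a gene, the fold is given as a lower bound against a floor of 3 reads over the group of 3 libraries. Such bounds, and statements about reads, cover counting error only, since amplified reads without molecular identifiers are not independent molecules.

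Gene IDs were matched to a RefSeq table of the GRCm38.p6 assembly, the same primary assembly as mm10, and coordinates are those of that table, printed only for IDs that matched. Symbols are printed as the tables give them, some of them older ones: Fam38b is Piezo2, Accn2 is Asic1, Accn3 is Asic3, Fam19a4 is Tafa4, Scn2a1 is Scn2a and Beta-s is Hbb-bs.

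The 3 candidate sets were genes higher than in Rx3-/-;PV:tdT in both other groups (proprioceptor candidates), genes lower in TrkC:GFP than in both PV:tdT groups (rapidly adapting candidates), and genes higher in TrkC:GFP than in both (slowly adapting candidates). Each set joins 2 comparisons that share a group. Beside each overlap stand the value from 100 simulated draws of unchanged groups with a shared control and the overlap of independent lists. A group of 3 libraries cannot be split so that each part keeps 2, so part of an excess may come from the shared controls.

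The 27 gene lists held markers of proprioceptors, of rapidly adapting mechanoreceptors (RA-LTMRs), of nociceptors with itch and C-fibre low-threshold neurons, of glia, endothelial and mural cells, fibroblasts and meninges, immune cells, erythroid cells and muscle, genes of the cell cycle, immediate early and dissociation stress, axon injury, immature neurons and mature large-diameter neurons, potassium, sodium and calcium channels, mechanotransduction candidates, ionotropic receptors, neurotrophic factor receptors, cadherins, guidance genes, somatosensory transcription factors, Hox genes in 3 lists, and Y-linked genes with Xist. For each list with 5 or more members with reads, members called in each direction were counted over all genes and adjusted over the list alone. As a description only, the list's median log2 fold change was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. Random lists kept the fitted values of genes without reads, so medians with such genes at their bound are not placed among them. On simulated data for comparison 1, over 23038 genes with 200 of them shifted by 1 on the log2 scale, 12 of 20 shifted lists of 10 genes lay above the central 95% of random lists, and 2 of 20 unshifted lists lay outside it.

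Genes named in the text followed 1 rule. For comparisons 1 to 3 these were the 8 genes per direction with the smallest p among those called with an absolute log2 fold change of 1 or more and a symbol that is not a predicted name. For comparisons 4 and 5 and each set they were the 6 smallest. Runx3, Pvalb, Ntrk3, Ntrk2, Etv1, Whrn, Ret, Maf and Mafa were added whatever their p, as were up to 4 called members of each list. Any other gene named was chosen after its values were seen: the kidney genes, Ren2, E430016F16Rik, the genes of the chromosome 13 segment, and members of lists named beside their calls.

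Other settings tried were a minimum mean log2 CPM of 0, an adjusted p of 0.01, and an absolute log2 fold change of 1 with the adjusted p of 0.05. Added after seeing the data were the authors' own flag, leaving out genes without reads in a group, a minimum RPKM of 1, leaving out a chromosome 13 segment, leaving out genes read in the deeper Rx3-/-;PV:tdT libraries alone, the list mean in place of the median, and the ratio of the deposited RPKM values. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.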

Results

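Transcriptomes were measured in 3 populations of sorted mechanosensory neurons from neonatal mouse dorsal root ganglia, with 3 samples per group. TrkC:GFP neurons came from a line carrying a bacterial artificial chromosome that expresses GFP under Ntrk3 (TrkC) control, and held proprioceptors together with slowly adapting low-threshold mechanoreceptors (SA-LTMRs). Rx3+/+;PV:tdT neurons were marked with tdTomato through Cre expressed from the parvalbumin gene in animals wild-type for Runx3, and held proprioceptors together with rapidly adapting mechanoreceptors (RA-LTMRs). Rx3-/-;PV:tdT neurons were marked in the same way in Runx3 mutants, in which proprioceptors do not survive, and were taken to hold RA-LTMRs. These groups are called the TrkC, wild-type PV and mutant PV groups below. Setting the 3 against each other asks which genes belong to each kind of neuron.

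Totals of counted reads recovered from the deposited RPKM values were 12.2, 10.5 and 7.8 M reads in the TrkC group, 13.7, 12.2 and 11.6 M in the wild-type PV group, and 12.8, 12.2 and 4.5 M in the mutant PV group. They are smaller than the read numbers that the labels give per sample, and which reads the RPKM values count is not stated. The shallowest mutant library thus held 0.35 of the reads of the deepest in its group. Reads were present in at least 1 group for 18068 genes. Of all genes in the tables, 6094 had none in the TrkC group, 6377 none in the wild-type PV group and 6339 none in the mutant PV group. Age differed between the groups. Pups were sampled at postnatal day 6, 2 and 1 in the TrkC group (mean 3.0), at day 6, 4 and 3 in the wild-type PV group (mean 4.33) and at day 3, 0 and 0 in the mutant PV group (mean 1.0). These ages overlap between groups, but with 1 deposited value per group the effect of age could not be separated from that of the group.

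The genes that define the groups came first. Runx3 (chromosome 4, 135120645 to 135177990, GRCm38.p6) had a deposited RPKM of 33.8 in the TrkC group, 30.4 in the wild-type PV group and 13.5 in the mutant PV group. By the authors' deposited table its log2 fold change over the mutants was 1.32 for TrkC neurons (edgeR adjusted p = 3.9e-08) and 1.16 for wild-type PV neurons (adjusted p = 2.8e-07). Reads over the whole gene were summed, so the values do not show whether the remaining mutant reads fall in the disrupted part. Pvalb (chromosome 15, 78191112 to 78206400), whose Cre drives the tdTomato reporter, was at 353, 200 and 67.0 RPKM in the TrkC, wild-type PV and mutant PV groups. Ntrk3 (chromosome 7, 78179986 to 78581034) was at 141, 81.6 and 25.4 RPKM in the same order. Y-linked Ddx3y, Kdm5d and Uty and the X-inactivation transcript Xist had reads in all 3 groups, as groups holding both sexes would give. In the same order, Ddx3y was at 14.1, 9.13 and 8.55 RPKM, Kdm5d at 3.6, 2.0 and 2.47 and Uty at 4.25, 3.01 and 3.6. Xist was at 4.89, 7.61 and 11.2 RPKM. The Y-linked genes were thus highest and Xist lowest in the TrkC group, although none of these was called in comparisons 1 to 3. The groups may not hold the sexes in equal shares. The tables give 1 value per group for these genes, so single samples could not be checked.

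**Figure D1:**
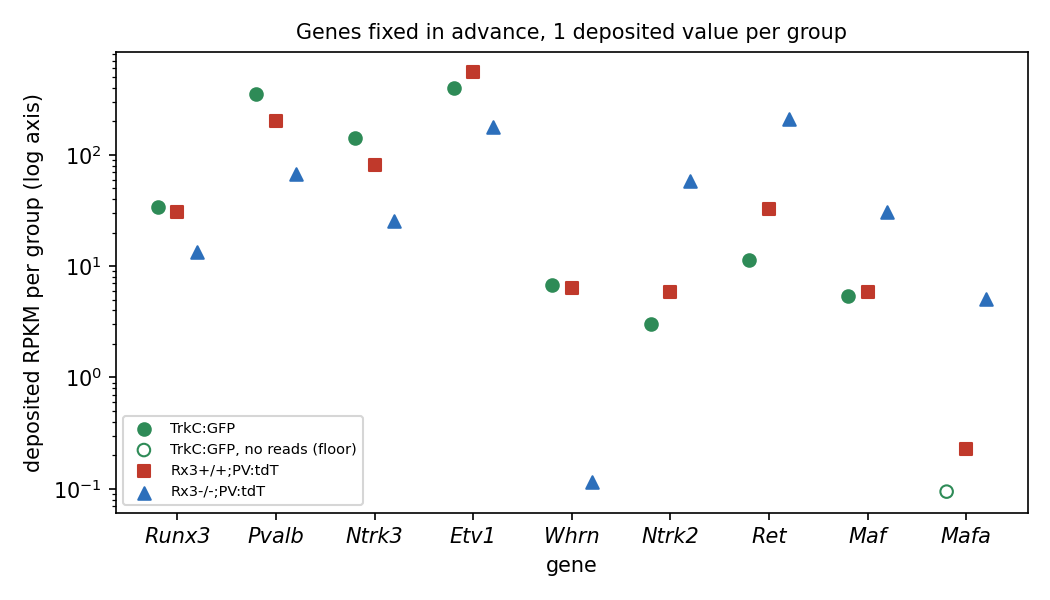
Deposited RPKM (log axis) of 9 genes chosen in advance, 1 group value per gene for TrkC:GFP (circles), Rx3+/+;PV:tdT (squares) and Rx3-/-;PV:tdT (triangles); an open circle marks a group without reads. Runx3, Pvalb, Ntrk3, Etv1 and Whrn lie lowest in the mutants, and Ntrk2, Ret, Maf and Mafa lie highest there.

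The comparison of TrkC with mutant PV neurons set proprioceptors and SA-LTMRs against RA-LTMRs. The reporter line, the Runx3 genotype and the mean age differ between these groups as well. Higher in TrkC neurons were Plxnd1, a plexin receptor, and the secreted guidance ligand Slit2, with deposited RPKM of 48.5 against 1.88 and 50.1 against 4.09. Wls, which carries Wnt proteins to the cell surface, was at 27.5 against 1.18, and the heparan sulfate enzymes Ndst4 and Hs3st2 were at 57.1 against 4.64 and 54.2 against 2.47. Vstm2b, an immunoglobulin-domain membrane protein gene, had 448, 549 and 313 reads in the 3 TrkC libraries and none in any mutant library. It was at least 338-fold higher in the TrkC group. In the opposite direction, Ntng1 (netrin-G1), the hyaluronan receptor gene Layn, the transcription factor gene Tbx3 and the receptor tyrosine kinase gene Ret were at 48.8, 107, 60.2 and 211 RPKM in mutant PV neurons and at 1.0, 4.41, 4.39 and 11.4 in TrkC neurons.

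At an adjusted p under 0.05 in the authors' deposited table, 2321 genes differed between these groups, 1353 higher and 968 lower in TrkC neurons. Of these, 981 and 740 differed by 2-fold or more. The log2 fold changes in that deposited table were 4.66 for Plxnd1 (edgeR adjusted p = 3.4e-63), 4.53 for Wls (3.6e-59), 3.62 for Ndst4 (6.6e-59), 3.62 for Slit2 (3e-52), 4.52 for Hs3st2 (2.5e-50), 5.65 for the orphan receptor gene Gprc5b (5.6e-48) and 3.86 for the actin-bundling gene Lcp1 (3.4e-47). On the other side, the authors' deposited table gave -4.59 for Layn (1.3e-67), -4.71 for the alpha-tubulin gene Tuba1c (3.6e-64), -5.59 for Ntng1 (8.4e-62), -3.94 for Chodl (1.4e-47), -3.78 for Tbx3 (4.6e-47), -7.09 for H60b (1.7e-45) and -4.21 for Ret (1.7e-42). Tuba1c and H60b have near-identical relatives with which reads can be shared, so their levels are less certain.

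Proprioceptor markers were higher in TrkC neurons than in mutant PV neurons. Of 12 measured, 8 were called higher and 0 lower over all genes, and 9 higher and 1 lower adjusted over the list alone. Their median log2 fold change of 1.88 lay at percentile 100.0 of random matched lists. Whrn, which encodes the scaffold protein whirlin (chromosome 4, 63414908 to 63496083), led with a log2 fold change of 5.81 in the authors' deposited table (edgeR adjusted p = 3.8e-31), from 0.114 RPKM in mutants to 6.84. By the same authors' deposited table Pvalb was at 2.39 (1.4e-14), Ntrk3 at 2.47 (9.9e-13) and Etv1, an ETS transcription factor gene, at 1.16 (2.4e-06). Chad had no reads in mutants and was at least 46.3-fold higher.

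RA-LTMR markers moved the other way, with 2 higher and 8 lower of 14 over all genes, 3 higher and 8 lower adjusted over the list alone, and a median of -2.87 (percentile 0.0). The authors' deposited table gave log2 fold changes of -4.27 for Ntrk2 (edgeR adjusted p = 1.2e-24), the receptor of brain-derived neurotrophic factor, -2.53 for the transcription factor gene Maf (1.2e-25) and -3.22 for the calcium channel gene Cacna1h (3.4e-16). Mafa had no reads in TrkC neurons and was at least 52.4-fold higher in mutant PV neurons. The 2 members called higher in TrkC neurons were Slit2 and the cell adhesion gene Cntnap2, the latter at 1.02 in the authors' deposited table (edgeR adjusted p = 4.8e-06).

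Among families of signalling genes, somatosensory transcription factors had 8 members higher and 18 lower of 50 (12 and 22 adjusted over the list alone, median -0.37, percentile 0.0). Bcl11a was higher at 4.74 and Tshz2 at 2.66, and Maf and Etv5 were lower at -2.53 and -2.4, in the authors' deposited table. Neurotrophic factor receptors had 2 higher, Ntrk3 and Kit, and 9 lower of 24 (5 and 9 over the list alone, median -0.49, percentile 0.0). Cadherins had 10 higher and 3 lower of 31 (11 and 3 over the list alone, percentile 97.7), led in the authors' deposited table by Cdh8 at 3.84 and Cdh20 at 4.17, with Pcdh17 at -1.51. Guidance genes had 17 higher and 9 lower of 62 (20 and 11 over the list alone, percentile 59.5), with Dcc and Sema3a at 3.28 and 3.4 and Plxna4 and Nrp1 at -2.86 and -2.07 in the authors' deposited table.

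Channels and receptors went in both directions. Potassium channel genes had 9 higher and 7 lower of 35 (9 and 7 adjusted over the list alone, percentile 66.4), with Kcns1 at 3.37 and Kcnc1 at 1.66 against Kcnh5 at -1.93 in the authors' deposited table. Sodium channel genes had 2 higher and 3 lower of 14 (3 and 4 over the list alone, percentile 1.9), with Scn1a at 1.41 and Scn10a at -1.72 in the authors' deposited table. Of 23 calcium channel genes 4 were higher and 7 lower (5 and 8 over the list alone, percentile 0.2), and Cacna1i rose from 0.0155 RPKM in mutants to 2.86. Mechanotransduction candidates had 3 higher and 4 lower of 22 (5 and 5 over the list alone, percentile 16.1). By the authors' deposited table Accn2, an acid-sensing channel gene, was at 1.4, and Fam38b, which encodes the mechanically gated channel Piezo2, was at -0.92 (edgeR adjusted p = 1.6e-05). Ionotropic receptor genes had 6 higher and 8 lower of 44 (8 and 11 over the list alone, percentile 12.1), with Chrna3 at 3.46 and the serotonin receptor genes Htr3a and Htr3b at -3.73 and -3.7 in the authors' deposited table.

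Markers of other neurons and cells also moved. Of 21 nociceptor, itch and C-fibre markers 3 were higher and 6 lower in TrkC neurons (6 and 7 adjusted over the list alone, median -0.32, mean 0.37, percentile 1.0). Calca, the gene of the peptide CGRP, was at 97.3 RPKM in mutant PV neurons and 1.74 in TrkC neurons, and the ATP receptor gene P2rx3 at 204 and 37.3, while Trpm8, the cold receptor gene, had no reads in mutants and was at least 143-fold higher in TrkC neurons. Glial markers had 3 higher and 1 lower of 18 (3 and 1 over the list alone, percentile 63.3). Endothelial and mural markers had 0 and 2 of 13 (0 and 4, percentile 0.1). Fibroblast and meningeal markers had 1 and 4 of 10 (2 and 4, percentile 32.2) and immune markers 1 and 0 of 12 (1 and 0, percentile 79.5). Erythroid markers had 0 and 1 of 5 (0 and 2, median -2.5 as fitted and -0.61 with genes without reads at their bound). Muscle markers had 1 and 0 of 7 (1 and 0, percentile 83.0). Called members included the myelin gene Mbp, Fcer1g and Myh8 (higher), and Pmp22, Emcn, Rgs5, Mgp and Beta-s (lower). In the mutant libraries, deepest first, Emcn had 56, 78 and 0 reads and Beta-s 18, 25 and 0. These calls thus rest on the deeper mutant libraries. Reads per library were not recovered for Pmp22, Rgs5 and Mgp. Cell cycle genes had 0 higher and 2 lower of 12 (0 and 3, percentile 0.1), stress genes 0 and 2 of 17 (0 and 2, percentile 97.2) and axon injury genes 0 and 2 of 11 (0 and 2, percentile 59.9).

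Genes of immature neurons were lower in TrkC than in mutant PV neurons for 4 of 15 members and higher for 0 (5 and 0 adjusted over the list alone, median -0.48, percentile 0.0), with Nnat at 35.1 and 156 RPKM. Genes of mature large-diameter neurons had 5 higher and 1 lower of 17 (6 and 4 over the list alone, percentile 93.7). The mutant animals were 2.0 days younger on average. Hox genes 1 to 4 had 1 higher and 1 lower of 11 (2 and 2, percentile 2.6), Hox genes 5 to 9 had 4 and 6 of 15 (5 and 6, percentile 0.0) and Hox genes 10 to 13 had 2 and 0 of 8 (3 and 0). The Hox 10 to 13 median was 3.85 as fitted and 0.76 with genes without reads at their bound. Of the Y-linked genes and Xist, 1 of 5 was called, Eif2s3y, higher in TrkC neurons (1 and 0 over the list alone, percentile 97.1). List medians and means had opposite signs for the nociceptor, fibroblast, axon injury, calcium channel, mechanotransduction and Hox 5 to 9 lists.

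Genes with known kidney expression were read in mutant PV libraries, beside the genes called lower in TrkC neurons; those named here were chosen after their values were seen. Ren2, a renin gene, had 641 and 849 reads in the 2 deeper mutant libraries and 0 in the shallowest, with no reads in the other groups. The podocyte gene Nphs1 had 122, 94 and 0 reads and the kidney tubule gene Umod 62, 67 and 0 in the same order. Of the 67 genes called lower that had no reads in TrkC neurons, 36 were read in those 2 deeper mutant libraries and not in the shallowest, although its depth would have given more than 3 reads. Of the 127 genes called higher that had no reads in mutants, 121 had reads in all 3 TrkC libraries.

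**Figure D2:**
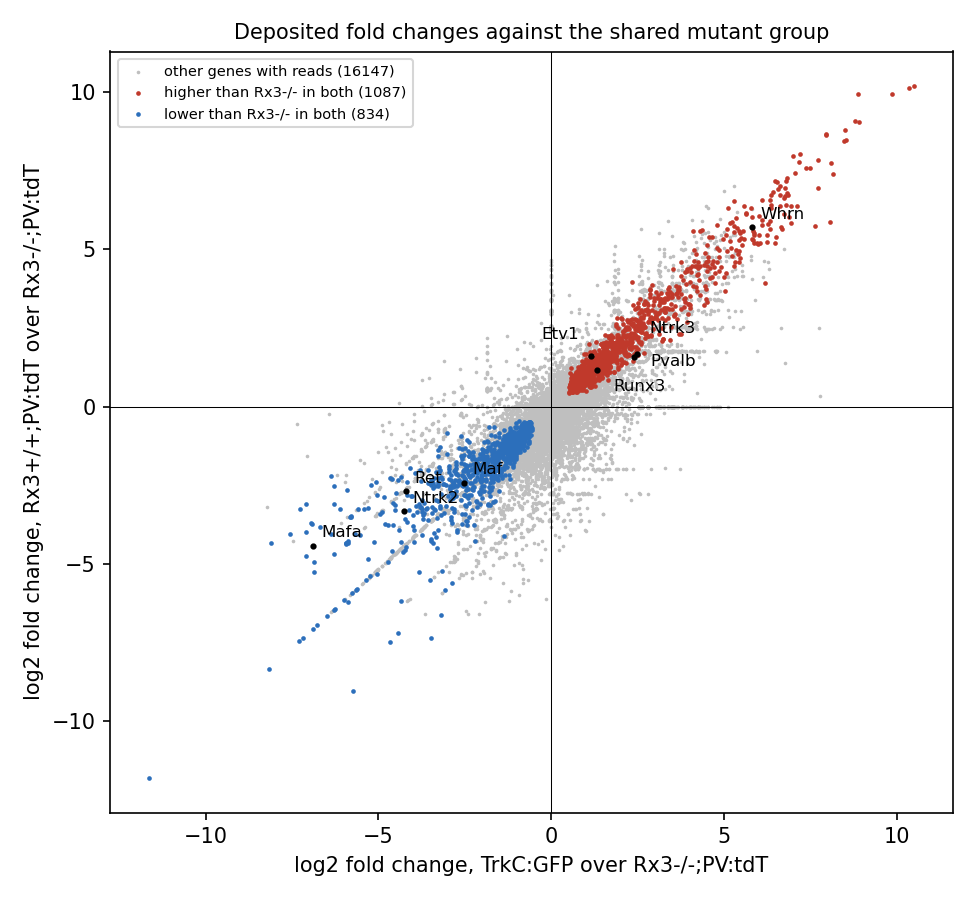
Deposited log2 fold changes over Rx3-/-;PV:tdT, with TrkC:GFP on the x axis and Rx3+/+;PV:tdT on the y axis, 1 point per gene with reads; genes without reads in a group stand at the authors' fitted value, which forms the straight streaks. Red marks 1087 genes called higher than in the mutants in both comparisons and blue 834 called lower in both.

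The comparison of wild-type with mutant PV neurons held the reporter fixed and asked what proprioceptors add to RA-LTMRs. The genes higher in wild-type PV neurons with the smallest p were largely those found with TrkC neurons: Ndst4 at 67.1 against 4.64 RPKM, Wls at 32.1 against 1.18, Gprc5b at 30.6 against 0.467, Plxnd1 at 44.7 against 1.88, Lcp1 at 144 against 7.55 and Vstm2b, at least 349-fold higher, with 464, 608 and 570 reads against none. The metabotropic glutamate receptor gene Grm3 was at 23.5 against 0.978 and the growth factor gene Fgf9 at 20.6 against 0.837. Higher in mutants were Trp53i11 at 29.6 against 2.51, Tbx3 at 60.2 against 6.57, the adaptor gene Shc4 at 24.0 against 4.42, the carbonic anhydrase gene Car3 at 41.3 against 4.33, Cd24a at 280 against 55.1 and Tle4, a co-repressor gene, at 40.0 against 6.81.

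The authors' deposited table called 3776 genes in this comparison, 1801 higher and 1975 lower in wild-type PV neurons, with 1041 and 1331 differing by 2-fold or more. Its log2 fold changes, as the authors' deposited table gives them, included 3.85 for Ndst4 (edgeR adjusted p = 1.3e-88), 4.76 for Wls (3e-88), 6.16 for Gprc5b (3.1e-82), 4.53 for Plxnd1 (2.6e-76), 4.27 for Lcp1 (3.6e-76), 4.64 for Grm3 (7.6e-72) and 4.61 for Fgf9 (1.6e-65). For genes higher in mutants the authors' deposited table gave -3.56 for Trp53i11 (7.4e-40), -3.2 for Tbx3 (2.5e-35), -2.44 for Shc4 (3.1e-34), -2.34 for Cd24a (8.6e-31), -3.26 for Car3 (6e-30) and -2.55 for Tle4 (1.7e-27). The ribosomal RNA gene Rn45s was among them at -2.51 (2.9e-34) in the authors' deposited table, with 5970, 1670 and 9500 RPKM in the TrkC, wild-type PV and mutant PV groups, as was Lars2 at -2.88 (4.8e-33), with 219, 43.4 and 319. Ribosomal RNA reads in poly-A selected libraries vary with RNA handling.

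Of the proprioceptor markers, 10 were higher and 1 lower of 12 in wild-type PV neurons (11 and 1 adjusted over the list alone, median 1.69, percentile 100.0). In the authors' deposited table Whrn was at 5.71 (edgeR adjusted p = 8.7e-34), Etv1 at 1.61 (1.1e-14), Pvalb at 1.57 (1.5e-07), Ntrk3 at 1.69 (8.1e-07), and Pou4f3 was the member called lower, at -0.98 (0.0438). Of the RA-LTMR markers 2 were higher and 8 lower of 14 (2 and 9 over the list alone, median -2.18, percentile 0.0). The authors' deposited table placed Maf at -2.41 (5.1e-24), Ntrk2 at -3.32 (6.7e-24), Ret at -2.69 (1.5e-19) and Mafa at -4.41 (6.9e-11). RA-LTMRs are taken to be part of both groups here and a larger share of the mutant group. The Runx3 genotype and the age of the animals differ too, so the reason for the higher markers in mutants cannot be told apart.

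Transcription factors had 9 higher and 21 lower of 51 (9 and 23 adjusted over the list alone, percentile 0.0). Neurotrophic factor receptors had 2 and 9 of 24 (4 and 10, percentile 0.0) and cadherins 11 and 4 of 31 (11 and 6, percentile 70.4). Guidance genes had 17 and 16 of 63 (18 and 17, median 0.16 as fitted and 0.0 with genes without reads at their bound). Potassium channel genes had 8 higher and 8 lower of 36 (9 and 9, percentile 46.7), sodium channel genes 3 and 3 of 14 (3 and 4, percentile 21.9), calcium channel genes 5 and 9 of 23 (6 and 10, percentile 0.2), mechanotransduction candidates 3 and 4 of 22 (3 and 4, percentile 88.3) and ionotropic receptor genes 5 and 8 of 44 (5 and 9, percentile 61.8). The leading members were largely those of the TrkC comparison: by the authors' deposited table Bcl11a was at 3.93, Ngfr at -1.92, Cdh7 at 3.57, Dcc at 3.13, Kcns1 at 3.56, Scn1a at 1.58, Cacna1i at 8.44, Accn3 at -1.18 and Htr3b at -3.43.

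Immature neuron genes were lower in wild-type PV neurons for 9 of 15 and higher for 0 (9 and 0 adjusted over the list alone, median -0.71, percentile 0.0). The migration gene Dcx was at -2.07 in the authors' deposited table, and Nnat was at 17.1 RPKM against 156 in mutants. Mature neuron genes had 7 higher and 1 lower of 17 (8 and 1, percentile 91.7), with the nuclear receptor gene Esrrg at 3.8 in the authors' deposited table. The wild-type animals were 3.33 days older on average. Nociceptor markers had 5 higher and 7 lower of 21 (6 and 10, median -0.48, mean 0.33, percentile 4.9). Glial markers had 2 and 3 of 18 (2 and 4, percentile 17.2) and endothelial and mural markers 0 and 4 of 14 (0 and 9, percentile 0.3). Of the called endothelial and mural markers, Cldn5 had 10, 15 and 0 reads in the mutant libraries, deepest first. Reads per library were not recovered for the others. Fibroblast markers had 4 and 4 of 10 (5 and 4), at percentile 100.0 by the median of 0.85 but 75.3 by the mean of 0.08. Immune markers had 1 and 0 of 12 (1 and 0, percentile 65.6). Erythroid markers had 0 and 2 of 5 (0 and 3, median -3.23 as fitted and -1.64 at the bounds) and muscle markers 0 and 0 of 7 (0 and 0, percentile 80.5). Cell cycle genes had 0 higher and 3 lower of 12 (0 and 3, percentile 19.1), stress genes 1 and 4 of 17 (1 and 4, percentile 46.1), axon injury genes 0 and 3 of 12 (0 and 3, percentile 41.7), and none of the 5 Y-linked genes and Xist was called. Medians and means differed in sign for the nociceptor, glial, immune, potassium channel and calcium channel lists. Of the 93 genes called lower that had no reads in wild-type PV neurons, 47 were read in the 2 deeper mutant libraries and not in the shallowest where more than 3 reads would have been expected from its depth.

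**Figure D3:**
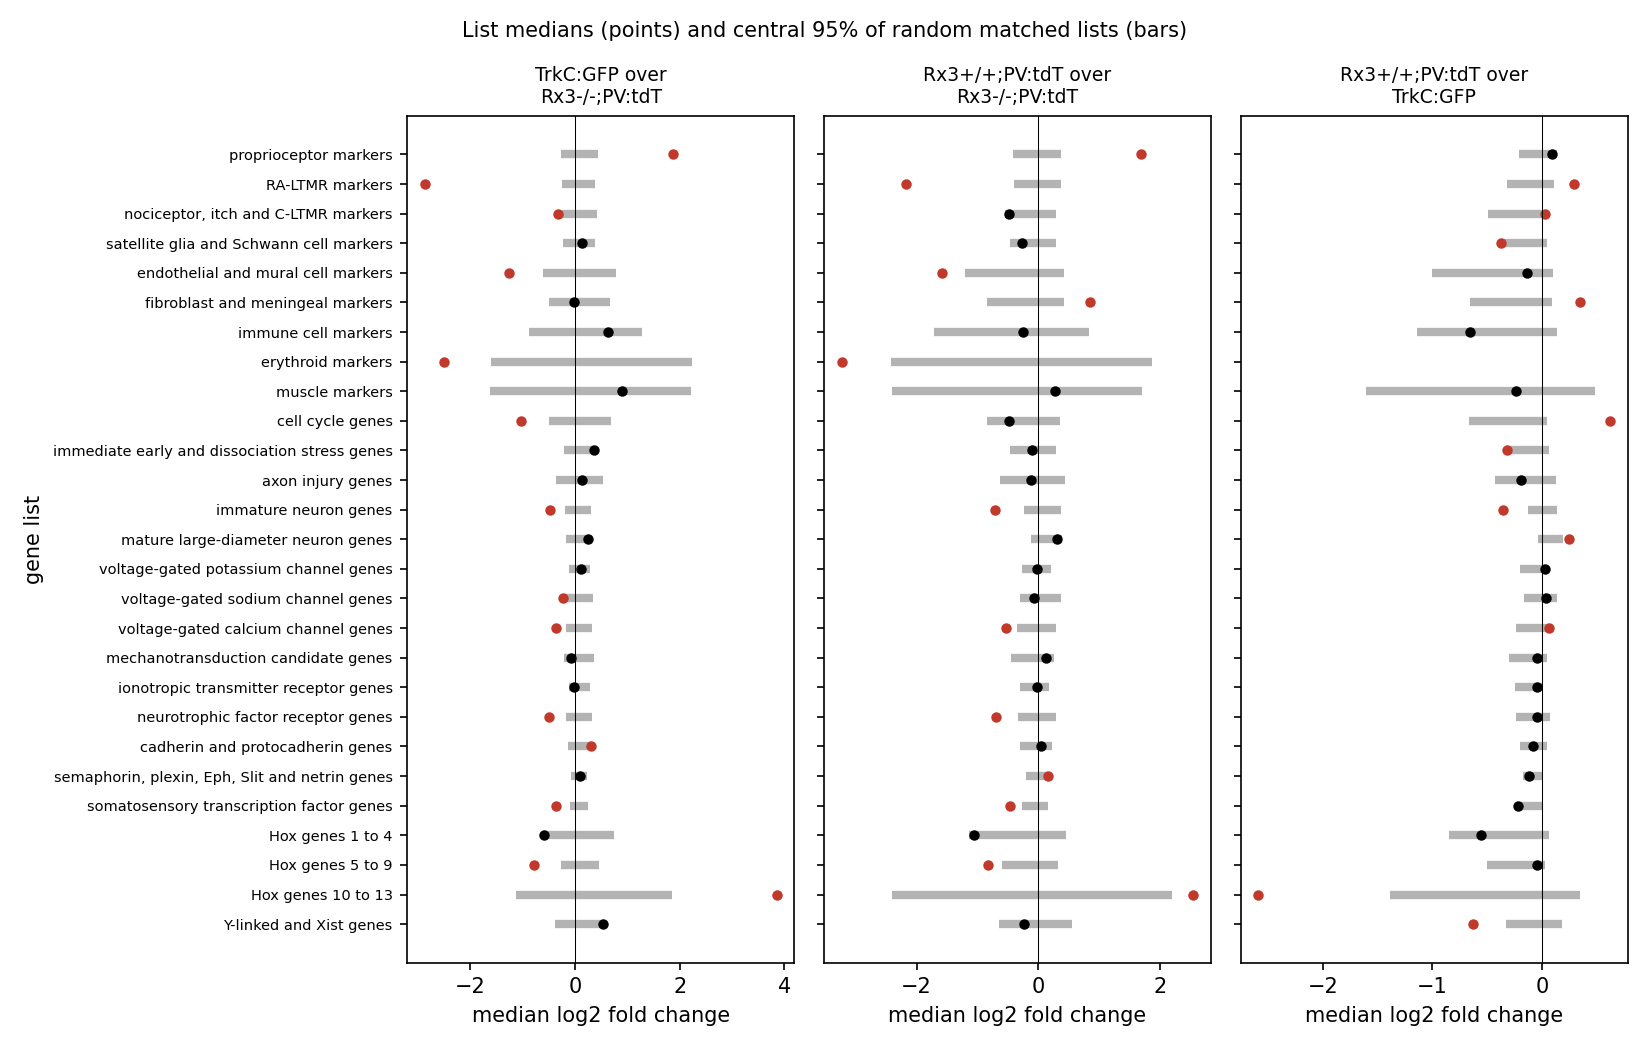
Median log2 fold change of each gene list (points) and the central 95% of random lists matched on mean expression (bars) in the comparisons of TrkC with mutant, wild-type with mutant, and wild-type PV with TrkC neurons; red points lie outside the bar, and genes without reads stand at the authors' fitted value. With such genes at their bound, the erythroid and Hox 10 to 13 medians are smaller in size wherever shown, as is the guidance median of wild-type over mutant PV neurons. The bars keep the fitted values, so bounded medians cannot be placed against them. Proprioceptor markers lie to the right and RA-LTMR markers to the left of the bars in both comparisons with mutants.

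The comparison of wild-type PV with TrkC neurons set RA-LTMRs against SA-LTMRs on a shared background of proprioceptors. The reporter line and the mean age differ between these groups too. Their effects cannot be told apart from that of neuron type. Higher in wild-type PV neurons were Tuba1c at 76.7 against 4.07 RPKM, Ift27 at 32.8 against 4.51, the GABA receptor gene Gabra2 at 38.0 against 8.54, the thrombin receptor gene F2r at 16.7 against 1.71, Calca at 8.63 against 1.74 and the integrin gene Itga2 at 32.1 against 10.3. Higher in TrkC neurons were the steroid reductase gene Srd5a2 at 13.8 against 0.358, the homeobox gene Hoxd1 at 4.86 against 0.62, the myosin gene Myh8 at 1.53 against 0.187, and the collagen genes Col19a1, Col6a3 and Col25a1 at 2.42, 0.988 and 1.12 against 0.411, 0.205 and 0.269. In mutant PV neurons Tuba1c, Gabra2, F2r and Calca were at 107, 38.2, 104 and 97.3 RPKM, but Ift27 and Itga2 at 7.8 and 2.02. Srd5a2, Hoxd1, Myh8, Col19a1, Col6a3 and Col25a1 were at 1.38, 2.41, 0.108, 1.24, 0.0168 and 1.53 there. Ift27 and Itga2, low in mutants, and Col25a1, higher there than in TrkC neurons, were thus not set apart by RA-LTMRs against SA-LTMRs alone.

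Fewer genes were called than against the mutants: 640 in the authors' deposited table, 161 higher and 479 lower in wild-type PV neurons, with 88 and 321 differing by 2-fold or more. The authors' deposited table gave log2 fold changes of 4.23 for Tuba1c (edgeR adjusted p = 2e-95), 2.85 for Ift27 (1.7e-46), 2.15 for Gabra2 (1.1e-25), 3.34 for the cystine transporter gene Slc7a11 (7.9e-24), 2.31 for Layn (2.6e-13), 3.28 for F2r (2.9e-13), 2.28 for Calca (4.3e-09) and 1.63 for Itga2 (4.4e-09). In favour of TrkC neurons the authors' deposited table gave -5.26 for Srd5a2 (4e-24), -2.55 for Col19a1 (5.5e-15), -2.97 for Hoxd1 (6.2e-12), -1.73 for Gda (6.1e-11), -3.03 for Myh8 (2.7e-10), -2.26 for Col6a3 (3.9e-10), -2.05 for Col25a1 (6.2e-09) and -1.39 for Tspan8 (6.8e-09).

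Runx3 was at -0.15 (edgeR adjusted p = 0.876), Whrn at -0.1 (1.0), Maf at 0.12 (1.0) and Ntrk2 at 0.95 (0.202) in the authors' deposited table and were not called. Mafa, without reads in TrkC neurons, was not called either (0.446 in the authors' deposited table). Pvalb and Ntrk3 were lower in wild-type PV neurons at -0.82 (5.4e-05) and -0.79 (3.6e-05), and Etv1 and Ret higher at 0.46 (0.0309) and 1.52 (2.5e-04), by the authors' deposited table. Of 12 proprioceptor markers, 2 were higher and 2 lower (2 and 2 adjusted over the list alone, percentile 92.2). Of 14 RA-LTMR markers, Ret was higher and Calb1 lower, against 5 and 2 adjusted over the list alone (median 0.29, percentile 100.0). Ionotropic receptor genes had 4 higher, Gabra2, Glrb, Gabrg1 and Chrnb3, and 1 lower of 45 (4 and 2 over the list alone, percentile 83.1). Immature neuron genes had 0 higher and 1 lower of 15 (0 and 1, median -0.36, percentile 0.0) and mature neuron genes 2 and 0 of 17, the neurofilament genes Nefm and Nefh (2 and 0, median 0.25, percentile 99.9). Glial markers had 0 called of 18 in either direction (percentile 1.8), and stress genes 1 higher, Hsp90aa1, and 2 lower, Fosb and Nr4a1, of 17 (1 and 3, percentile 2.2). By the median, fibroblast markers (2 higher and 1 lower of 10) and cell cycle genes (0 and 0 of 12) were at percentile 100.0. Nociceptor markers (1 and 3 of 21) were at 97.9 and calcium channel genes (0 and 1 of 23) at 97.6. Y-linked genes and Xist (0 and 1 of 5, 0 and 3 over the list alone) were at percentile 0.0. So were Hox genes 10 to 13 (0 and 0 of 8) as fitted.

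The comparison of TrkC neurons with both PV groups asked which genes mark the population that alone holds SA-LTMRs. That population is also the only one from the TrkC:GFP line, so line and neuron type cannot be told apart. Lower in TrkC neurons than in both PV groups were Tuba1c, Slc7a11, Gcnt4, F2r, Gabra2 and Layn, and higher were Myh8, Srd5a2, Gpr50, Rmst and Hotair. The noncoding RNA genes Rmst and Hotair were at 1.99 and 0.566 RPKM, and Gpr50 and Hotair, without reads in either PV group, were at least 24.8-fold and at least 11.1-fold higher. The prostaglandin synthase gene Ptgds was at 24.7 RPKM, but 606 of its TrkC reads were in 1 library, with 6 and 10 in the others.

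The authors' deposited table called 105 genes here, 39 higher and 66 lower in TrkC neurons. In the authors' deposited table the log2 fold changes were 3.36 for Myh8 (edgeR adjusted p = 1.1e-09), 4.01 for Srd5a2 (8.8e-08), 7.59 for Ptgds (5.6e-07) and 3.96 for Rmst (1.4e-05), against -4.49 for Tuba1c (1e-35), -3.24 for Slc7a11 (5.9e-12), -2.66 for Gcnt4 (2.1e-06), -5.13 for F2r (4.9e-06), -2.15 for Gabra2 (4.9e-06) and -3.87 for Layn (7.1e-06). Of the genes chosen in advance, Ret at -3.42 (0.00196) and Ntrk2 at -3.41 (0.0271) were called in the authors' deposited table. Not called there were Runx3 at 0.62 (0.796), Pvalb at 1.4 (0.0679), Ntrk3 at 1.39 (0.123), Etv1 at 0.14 (1.0), Whrn at 1.08 (1.0) and Maf at -1.78 (0.195), again from the authors' deposited table. Mafa, without reads in TrkC neurons, had an adjusted p of 0.065 in the authors' deposited table. RA-LTMR markers had 0 higher and 3 lower of 14, among them Ret and Ntrk2 (1 and 8 adjusted over the list alone, percentile 0.0). Nociceptor and C-fibre markers had 2 higher, Fam19a4 and Slc17a8, and 1 lower, Calca, of 21 (2 and 5, percentile 3.1). The PV groups differ from each other in proprioceptors, which adds to the spread of the joined groups.

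Joining the groups that hold proprioceptors against the mutants, the authors' deposited table called 3865 genes, 2032 higher and 1833 lower. In the authors' deposited table the 6 leading genes on the higher side were Wls at 4.65 (edgeR adjusted p = 8.3e-85), Plxnd1 at 4.6 (5.9e-82), Ndst4 at 3.74 (1.1e-77), Vstm2b, at least 343-fold higher (3.7e-77), Slit2 at 3.6 (1.4e-69) and the calcium channel gene Cacna1i at 8.46 (1.2e-68). On the lower side the authors' deposited table gave Shc4 at -2.56 (2.8e-52), Tbx3 at -3.46 (2.7e-46), Trp53i11 at -3.63 (2.7e-46), Tle4 at -2.69 (3.3e-42), Maf at -2.47 (1.4e-40) and the plexin gene Plxna4 at -2.88 (3.7e-38). Runx3 at 1.24, Pvalb at 2.04, Ntrk3 at 2.13, Etv1 at 1.4 and Whrn at 5.75 were called higher, and Ntrk2 at -3.72, Ret at -3.26 and Mafa at -5.11 lower, in the authors' deposited table. Proprioceptor markers had 10 higher and 1 lower of 12 (11 and 1 adjusted over the list alone, percentile 100.0) and RA-LTMR markers 2 and 8 of 14 (2 and 9, percentile 0.0).

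Crossing the comparisons gave candidate genes for each kind of neuron. Proprioceptor candidates, higher than in mutants in both other groups, numbered 1087, led by Plxnd1, Wls, Ndst4, Vstm2b, Slit2 and Hs3st2. RA-LTMR candidates, lower in TrkC neurons than in both PV groups, numbered 72, led by Layn, Tuba1c, Slc7a11, F2r, Gcnt4 and Serpina3n, a protease inhibitor gene at 5.68, 18.2 and 34.6 RPKM in the TrkC, wild-type PV and mutant PV groups. SA-LTMR candidates, higher in TrkC neurons than in both PV groups, numbered 91, led by Myh8, Srd5a2, Col6a3, Fam19a4, Slc27a6 and Syt17, the last a synaptotagmin gene at 12.3, 5.66 and 1.41 RPKM. A further 834 genes were higher in mutants than in both other groups, led by Ntng1, Tbx3, Trp53i11, Shc4, Car3 and Tle4. The sets are not exclusive: Pvalb (353, 200 and 67.0 RPKM in the same order) and Ntrk3 (141, 81.6 and 25.4) met the proprioceptor and SA-LTMR rules. Calca, listed as a nociceptor marker and at 1.74, 8.63 and 97.3 RPKM, met the RA-LTMR rule. A level graded across the 3 groups is enough to enter, so membership alone does not assign a gene to a kind of neuron. The RA-LTMR and SA-LTMR rules also set the TrkC:GFP line against both PV:tdT groups. A difference between the reporter lines would thus enter these sets too.

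Independent lists of these sizes would share 145.0, 9.0 and 38.4 genes for the 3 candidate sets and 107.8 for the genes higher in mutants. Simulated unchanged groups with a shared control gave 0 shared calls in all 100 draws. With no gene changed, adjustment leaves almost no calls, so this result was near certain and lends the overlaps no weight. The draws also do not cover a change in the shared group itself, which would enter both comparisons. At an unadjusted p under 0.05 the overlaps were 1811, 244, 454 and 1419 genes, against a simulated mean of 77.5. Those draws held no changed gene either, so any groups that differ would exceed it. This lends the overlaps no weight. Part of each excess may come from the shared controls.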

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

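Tests with the authors' own flag, without genes lacking reads in a group, at 1 RPKM or more, without the chromosome 13 segment, without genes read in the deeper mutant libraries alone, by list mean and by RPKM ratio were chosen after seeing the data. An adjusted p of 0.01 gave 2499 genes between wild-type and mutant PV neurons, 305 between wild-type PV and TrkC neurons, 49 between TrkC neurons and both PV groups, 37 RA-LTMR candidates and 43 SA-LTMR candidates. Requiring a 2-fold change at 0.05 gave 2372 genes between wild-type and mutant PV neurons, 409 between wild-type PV and TrkC neurons, 2328 between the joined groups and mutants, and 46 SA-LTMR candidates. The authors' own flag gave 1119, 1501, 164, 43 and 1369 genes for the 5 comparisons in order, with 487 proprioceptor, 24 RA-LTMR and 22 SA-LTMR candidates. These settings are stricter by construction, so fewer genes pass.

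Under a minimum mean log2 CPM of 0, the counts stayed within 1.5 times the reported ones (2386, 3811, 736, 142 and 3757 genes, with 1094, 81 and 119 candidates). Leaving out genes read in the deeper mutant libraries alone gave 2281, 3719, 639, 104 and 3803 genes, with 1087, 71 and 91 candidates. The other added settings also stayed within 1.5 times. Leaving out the chromosome 13 segment gave 82 SA-LTMR candidates in place of 91, while the 72 RA-LTMR candidates stayed. It also gave 462 genes higher in TrkC than in wild-type PV neurons in place of 479, while the 161 lower ones stayed. Of 701 named gene results, 643 passed an adjusted p of 0.01 or stayed on their side of it, 58 no longer passed, and 701 kept their sign by the ratio of deposited RPKM.

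No paired analysis was possible because values were deposited per group and not per sample. For the same reason leaving out each sample, an age covariate, other normalizations and pseudocounts, other splits of the samples and the remaining fits were not run. The shallowest mutant library, at 0.35 of the deepest, limits what can be read as absent from mutants.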

Other observations

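All tests in this part were chosen after the results they address were seen. Calls among Hox genes were counted by cluster, and no test of a difference between clusters was run. Of the Hoxc genes, 6 of 9 were higher in TrkC than in mutant PV neurons and 4 of 7 higher in wild-type than in mutant PV neurons, with 0 lower in both. Of the Hoxb genes, 5 of 8 and 6 of 9 were lower, with 0 higher. Hoxa genes had 1 higher and 2 lower of 10, and 0 and 3 of 9, and Hoxd genes 0 and 0 of 7, and 0 and 1 of 7. Hoxc8 was at 18.0, 20.1 and 1.78 RPKM in the TrkC, wild-type PV and mutant PV groups, Hoxc10 at 14.1, 12.0 and 0.806, and Hoxb8 at 0.777, 2.03 and 14.3. Which spinal levels went into each sample is not given.

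Immature neuron genes were lower in wild-type than in mutant PV neurons, whose mean ages differed by 3.33 days. Of the 17 mature neuron genes, 7 were called higher and 1 lower, and their median of 0.31 lay inside the random range (percentile 91.7). If age were the cause and acted in proportion, the 1.33 days between wild-type PV and TrkC neurons would carry 0.4 of the change. The immature genes had a median of -0.36 there (predicted -0.28, bootstrap range -0.45 to -0.14, 14 of 15 members in that direction), as the hypothesis that age contributes would give. Both comparisons share the wild-type PV group, so a shift of that group alone would also move both medians the same way. For mature genes the median was 0.25 (predicted 0.13, range 0.18 to 0.34). For the 1801 higher and 1975 lower genes it was 0.13 (range 0.11 to 0.14) and -0.32 (range -0.35 to -0.3). Both fell short of the predicted 0.46 and -0.55. All these ranges resample genes and leave out the spread between animals. The shortfall therefore does not settle whether age in proportion could be their whole cause. How much age adds and how much neuron type cannot be told apart for these genes, since the proportion is assumed, each comparison changes both, and values per sample were not used here.

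Kidney genes were read in 2 of the 3 mutant libraries, with 1156 and 1324 reads over 15 genes seen first against 0 in the shallowest. Other genes share this. Among genes without reads in at least 1 group, 156 had 15 or more recovered mutant reads. Of these, 74 had none in the shallowest library although its depth would give more than 3, kidney genes among them. The same counts were 9 of 136 and 5 of 139 in the TrkC and wild-type PV groups. Lung markers had 34, 4 and 0 reads in the mutant libraries. The endothelial marker Emcn had 56, 78 and 0 there and the erythroid marker Beta-s 18, 25 and 0. Expression in all 3 libraries, missed in 1 for its depth, would give the 15 kidney genes seen first 447 reads in the shallowest library. They were chosen after their values were seen, and Ren2 held 641 and 849 of their reads, so this value was not independent of the choice. Kidney markers not seen before they were listed, with 19, 34 and 0 reads, would have 9.6 there. Their values argue against a miss for depth alone. RNA of kidney cells in 2 libraries is a hypothesis: of 20 measured markers not seen before, 5 were higher in mutant than in wild-type PV neurons (Slc12a3, Aqp2, Lrp2, Slc5a12 and Fxyd2), against 4 of 26 markers of adrenal, liver, lung, intestine and pancreas (Fisher exact one-sided p = 0.328), while over TrkC neurons the counts were 1 and 3 (p = 0.908), so this cannot be told apart from other sources at such counts. Of the 23 markers not seen before they were listed, 3 were at 1 RPKM or more in wild-type PV neurons. Among them was Slc3a1 at 95.9, with 111.0 in TrkC and 85.5 in mutant PV neurons. Counting the 15 genes seen first as well, the most abundant kidney genes called higher in mutants were Ren2 at 26.1 RPKM, Fxyd2 at 7.75 and Klk1 at 5.32. Ren2 and Klk1 are among those 15. Sorting for tdTomato would remove kidney cells without the reporter, and the libraries cannot be matched to the samples by age.

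On chromosome 13, 30 neighbouring genes between 17695413 and 25252039 had a median log2 fold change of 0.83 in TrkC over mutant PV neurons, 0.4 in wild-type over mutant PV neurons and -0.49 in wild-type PV over TrkC neurons. A scan of wild-type PV over TrkC neurons took runs of 20 neighbouring genes at 3 log2 CPM or more. Its most extreme run, with gene starts from 18717292 to 24831659, had a median of -0.55 relative to all scanned genes. In a permutation test, 0 of 1000 shuffled gene orders gave a run as far from 0 (0.001, the smallest value it can give), which argues against chance. All 12 of the segment's less expressed genes, which did not define the segment, were higher in TrkC neurons, against 72.2% elsewhere (binomial p = 0.0202). This argues against variants acting on single genes only if the 12 genes vary independently, which neighbouring genes need not do. Neither test separates extra copies from other causes that neighbouring genes share. Extra copies of the segment in TrkC:GFP animals may contribute: those same 12 genes had a median of -0.96 in wild-type PV over TrkC neurons (percentile 0.09, random range -0.7 to 0.05). That the segment was also above the mutants in wild-type PV neurons is left open by this hypothesis, and no further explanation was tested.

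E430016F16Rik, which starts 32 bases beyond the end of Ntrk3, was at 37.7, 1.03 and 0.434 RPKM in the TrkC, wild-type PV and mutant PV groups. Apart from Ntrk3, 4 genes within 500 kb had a mean log2 CPM of 0 or more. Of these, 0 were called in TrkC neurons against both PV groups. Ntrk3 was not called there (1.39, edgeR adjusted p = 0.123). It was lower in wild-type PV than in TrkC neurons (-0.79, edgeR adjusted p = 3.57e-05). The TrkC:GFP line carries an artificial chromosome with Ntrk3 control, and its effect on either gene was not tested. Y-linked Eif2s3y was at 31.9, 14.5 and 12.4 RPKM in the TrkC, wild-type PV and mutant PV groups. It was highest in the TrkC group, as were Ddx3y, Kdm5d and Uty.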
